A study of Mus musculus with 21 samples.

How the data were processed

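The series measured gene expression in mouse B-lineage cells on Affymetrix Mouse Genome 430 2.0 arrays, with 1 array per sample and 21 arrays in 7 groups of 3. Per the labels, 4 groups were B220-positive bone marrow cells separated on a cell sorter, B220 being a surface marker of the B lineage. These cells came from wild-type mice, from mice carrying a Cebpb LAP transgene, from Blnk knockout mice and from mice with both changes. LAP is the activating isoform of the transcription factor C/EBPβ, and BLNK is the adaptor protein that links the pre-B cell receptor to its downstream kinases and phospholipase. The other 3 groups were LB31, a mouse pre-B acute lymphoblastic leukaemia line established from a Blnk knockout mouse, transduced with a pMY retroviral vector that was empty, carried Blnk cDNA, or carried a loss-of-function Blnk mutant named YF. The line was grown with 5 ng/ml of interleukin 7, per the labels. Biotin-labelled cRNA was made from 100 ng of total RNA, per the labels. Whether the replicates of a group came from separate animals or cultures is not given in the sources used here, so every p-value measures only the spread between these samples, which may be technical.

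The deposited values are probe set signals on a linear intensity scale that is never negative, and the submitters' processing notes name MAS5, with no version. Whether the authors scaled the arrays to a common target is not given in the sources used here. The plan fixed before the data were examined assumed that they had, and tested the values as deposited. The deposited intensity values were not on 1 scale: the trimmed mean of an array, leaving out 2% at each end, ran from 104.4 to 184.2, and the median from 15.3 to 31.4. The arrays were therefore quantile normalized on the log2 scale before any comparison of groups was run, a setting that the plan had listed as an alternative. Testing the values as deposited was kept as an alternative and entered the list of alternatives after the values had been seen. Quantile normalization removes any true difference in the overall amount of message between groups, and the median deposited signal did differ, at 21.5 ± 2.07 (SD, n = 3) in wild-type, 21.1 ± 0.265 in LAP transgenic, 28.8 ± 1.78 in knockout-labelled and 29.3 ± 1.87 in doubly labelled marrow. In LB31 it was 17.0 ± 2.23 with the empty vector, 16.7 ± 1.21 with BLNK and 18.4 ± 0.550 with YF.

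A pseudocount of 4 was added before taking log2. It is 0.2 of the median of all deposited values, 21.2, rounded to a whole number. Fold changes are on this scale and understate the change of dim genes. Of the 10 largest rises and 10 largest falls of a comparison, 6 and 2 had a lower group under the filter level for LAP knockout-labelled against wild-type marrow, 3 and 3 against knockout-labelled, 5 and 2 against LAP transgenic, 3 and 0 for BLNK against empty vector, 0 and 0 for YF against empty vector, and 3 and 2 for BLNK against YF. Arrays were normalized together within each fit: the 12 marrow arrays, the 9 LB31 arrays, or all 21 for the comparison of LB31 with marrow. A probe set entered a fit if its deposited value lay above its own array's 40th percentile on at least 3 arrays of that fit. On the normalized log2 scale that percentile was 4.05 in the marrow fit, 3.72 in the LB31 fit and 3.98 over all arrays. Of the 45101 probe sets, 64 were controls and were left out. Platform annotation gave 34945 of the others 1 gene symbol, 932 several and 9160 none here. Of those with 1 symbol, 34741 matched the mouse RefSeq gene table of assembly GRCm38.p6 by Entrez ID, which changed 0 symbols. Each of the 18193 genes was represented by its probe set with the highest mean log2 value over all 21 arrays, and 9010 genes had more than 1. Probe sets of a gene can disagree. Where a named gene had other probe sets, the number called in the opposite direction was 4 for LAP knockout-labelled against wild-type marrow, 5 for BLNK against empty vector, 37 for LB31 against marrow, and 0 in the other 7 comparisons. Other probe sets called in the same direction and not called numbered 78 and 57 for knockout-labelled and 9 and 18 for LAP transgenic against wild-type marrow. For LAP knockout-labelled marrow they numbered 137 and 48 against wild-type, 47 and 23 against knockout-labelled and 108 and 68 against LAP transgenic. They were 14 and 23 for the interaction, 58 and 66 for BLNK and 1 and 21 for YF against empty vector, 46 and 44 for BLNK against YF, and 178 and 59 for LB31 against marrow.

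Group means were fitted with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, with no covariate, and p-values were adjusted by Benjamini-Hochberg over the genes of a fit. A gene was called at an adjusted p under 0.05, and every adjusted p of a gene is from this test, two-sided, with log2 changes given ± SE and n = 3 arrays per group. The interaction is the LAP change in knockout-labelled marrow minus the LAP change in wild-type marrow.

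The rule for named genes was fixed before the data were examined: Blnk and Cebpb, the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between the groups, and the 4 members with the smallest adjusted p of each gene list described. Unnamed gene models and immunoglobulin segments were left out of the largest changes. For the interaction no separation was asked. Of any gene, 3 arrays against 3 separate completely by chance in 10% of cases. The 26 gene lists were also written in advance, from textbook markers of B-cell stages, of signalling and cell growth, and of the other cell types that marrow can hold. The light chain list takes every symbol that begins with Igk or Igl except Igll1, so it also holds Iglon5, an adhesion gene that is no light chain. Lists were tested with camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the arrays and with fry. Camera p-values were adjusted over the lists of a comparison, and counts of called members are given over all genes of the fit and adjusted over the list alone. Some listed genes had no probe set with 1 symbol and were not used here, among them Vpreb2, Ighd, Lyn and Isg15.

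The tests were run on simulated data with known answers before the real comparisons. Over the 10 comparisons, genes changed 1.5-fold were called in 30.8% to 67.7% of cases, genes changed 2-fold in 46.3% to 80.3%, and genes changed 4-fold in 79.4% to 96.8%. Between 2.96% and 7.79% of the calls were false. Alternatives tried were 2 other pseudocounts, the values as deposited, arrays centred on their median, no filter and a filter at the 60th percentile, the mean of a gene's probe sets, every probe set on its own, eBayes without the trend, array weights, other arrays in the fit, the replicate number as a block, and leaving out each array in turn. For comparisons against the same empty-vector arrays, 100 simulations with no effect gave the correlation that the shared controls alone produce. The labels carry replicate numbers but name no animal, litter or day.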

Results

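Transcript levels were measured on 21 arrays, 3 for each of 7 groups: sorted B220-positive marrow cells of 4 genotypes, which the series describes as non-neoplastic, and the LB31 pre-B leukaemia line with 3 vectors. The marrow groups are named wild-type, LAP transgenic, knockout-labelled (Blnk knockout) and LAP knockout-labelled (both changes). The LB31 groups are empty-vector, BLNK-labelled and YF-labelled. Replicate arrays of a group correlated with r between 0.966 and 0.984 over all probe sets. In the 12 marrow arrays 13347 genes passed the filter, in the 9 LB31 arrays 13024, and over all arrays 14653. Levels of Blnk, Cebpb and Xist by group are from all 21 arrays normalized together, while changes within marrow or within LB31 are from those arrays normalized on their own, so a change can differ from the difference of its levels.

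Blnk is represented by 1 probe set, and its signal did not follow the labels. Its mean normalized log2 signal was 12.44 ± 0.09 (SD, n = 3) in wild-type, 12.28 ± 0.16 in LAP transgenic, 12.37 ± 0.24 in knockout-labelled and 12.03 ± 0.14 in LAP knockout-labelled marrow. Knockout-labelled marrow differed from wild-type by -0.07 ± 0.11 (adjusted p = 0.761). In LB31 the signal was lower, at 9.63 ± 0.02 with the empty vector, 8.56 ± 0.06 with BLNK and 9.40 ± 0.08 with YF. Normalized within LB31, BLNK-labelled cells differed from empty-vector cells by -1.15 ± 0.06 (adjusted p = 2.34e-08). Where this probe set lies relative to the deleted part of the gene, and whether the introduced cDNA contains its target, is not given. It therefore checks neither the knockout nor the transduction, and every Blnk and BLNK comparison below rests on the labels.

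Cebpb has 2 probe sets, which differed. The one that represents the gene followed the LAP transgene: its mean log2 signal was 5.43 ± 0.10 (SD, n = 3) in wild-type, 10.05 ± 0.15 in LAP transgenic, 5.02 ± 0.35 in knockout-labelled and 9.90 ± 0.08 in LAP knockout-labelled marrow. LB31 had a signal as high as the transgenic marrow, 10.22 ± 0.10 with the empty vector, although its labels name no transgene. Its other probe set was not called in LAP transgenic against wild-type marrow (0.98 ± 0.39, adjusted p = 0.26) and was lower in empty-vector LB31 than in knockout-labelled marrow (-2.43 ± 0.40, adjusted p = 2.27e-05).

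**Figure D1:**
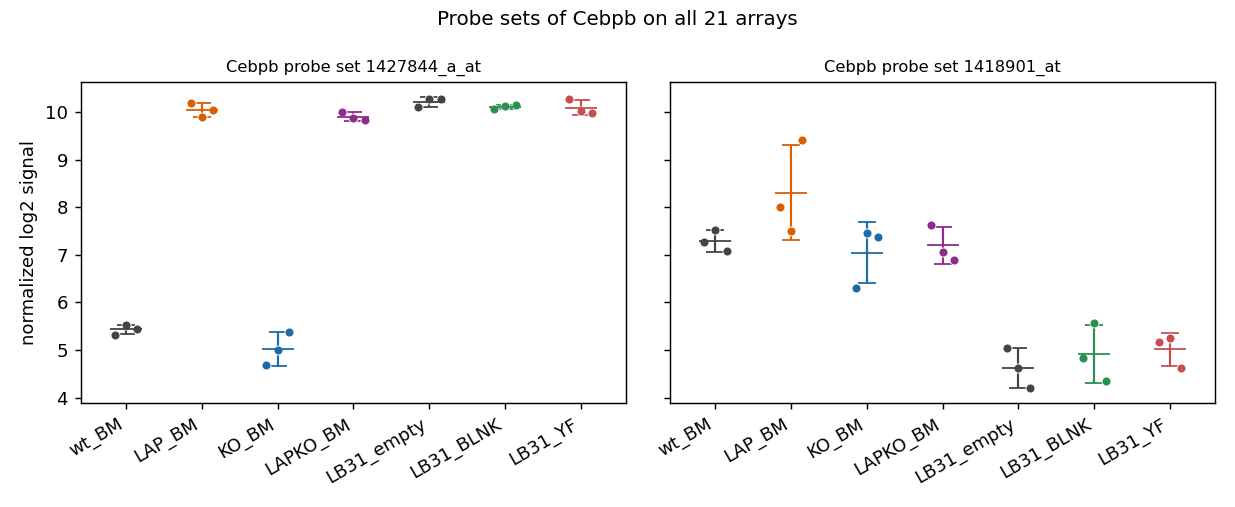
Normalized log2 signal of the 2 Cebpb probe sets on each of the 21 arrays, by group; points are arrays and bars are the group mean ± SD (n = 3). The representing probe set had group means of 10.05 and 9.90 in the LAP marrow groups, 10.22 in empty-vector LB31 and 5.43 and 5.02 in the other marrow groups, while the other probe set was lowest in LB31, with group means of 4.62, 4.92 and 5.02.

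Knockout-labelled against wild-type marrow asks which transcripts of B220-positive cells differ with the Blnk knockout label. Enpep, the BP-1 antigen of large pre-B cells, rose 12.3-fold (3.62 ± 0.19, adjusted p = 1.06e-07), and Erg, a transcription factor of early progenitors, rose 9.44-fold (3.24 ± 0.15, adjusted p = 8.76e-08). The IgM Fc receptor Fcmr fell by 2.82 ± 0.14 (adjusted p = 9.26e-08) and Brwd1, a chromatin reader used in kappa light chain recombination, fell by 2.79 ± 0.12 (adjusted p = 5.62e-08). Rasgrp1, which activates Ras downstream of antigen receptors, fell by 2.96 ± 0.12 (adjusted p = 5.49e-08), and Egr3, a transcription factor induced by receptor signals, fell by 2.94 ± 0.22 (adjusted p = 1.74e-06).

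Of 15 measured pro-B and large pre-B genes, 9 rose and 0 fell, or 9 and 1 adjusted over the list alone, with a median log2 change of 0.96. Camera gave an adjusted p = 3.2e-07 for this list, and an adjusted p = 0.304 with an estimated correlation. Its members included Igll1 (2.23 ± 0.15) and Vpreb1 (1.60 ± 0.11), the 2 parts of the surrogate light chain that pairs with the heavy chain in the pre-B cell receptor. Of 21 immature and mature B genes, 19 fell and 0 rose, on both counts, with a median of -1.43. Camera's adjusted p = 6.71e-20 became an adjusted p = 0.124 with an estimated correlation. Cd83, a surface marker of activated and maturing B cells, fell by 2.47 ± 0.12, and Ccr7, a chemokine receptor for entry into lymph nodes, fell by 1.93 ± 0.12. Among 13 genes of the immunoglobulin light chain list, 9 fell and 0 rose, or 10 and 0 adjusted over the list alone, with a median of -1.19. Camera's adjusted p = 1.67e-05 became an adjusted p = 0.0792 with an estimated correlation. Iglv1, a lambda variable segment, fell by 2.44 ± 0.18.

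Of 22 immediate early and activation genes 9 fell and 2 rose, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.0307, adjusted p = 0.556 with an estimated correlation). Beside Egr3, the phosphatase gene Dusp5 (-2.02 ± 0.25) and Egr1 (-1.20 ± 0.18) were among those that fell. In the B-cell receptor signalling list 7 of 17 genes fell and 1 rose, or 8 and 1 adjusted over the list alone, and camera did not call it (adjusted p = 0.127). The riser was the inhibitory lipid phosphatase Inpp5d (0.74 ± 0.07), while Ptpn6, an inhibitory tyrosine phosphatase, fell by 0.99 ± 0.11. Cell cycle genes rose in 5 of 28 cases and fell in 0, on both counts, among them the replication helicase gene Mcm3 (0.68 ± 0.14, adjusted p = 0.00551). Camera's adjusted p = 0.00699 for this list became an adjusted p = 0.722 with an estimated correlation. Thy1, a T-cell surface antigen, rose by 2.00 ± 0.28, and 4 of 15 genes of the T and NK cell list rose and 0 fell, on both counts (camera adjusted p = 0.0445, adjusted p = 0.555 with an estimated correlation). Of 15 MYC-responsive ribosome biogenesis genes 4 rose and 0 fell, or 5 and 0 adjusted over the list alone, with the polyamine enzyme Srm at 0.55 ± 0.10 (camera adjusted p = 0.0307, adjusted p = 0.555 with an estimated correlation). Left out in turn, single arrays ended 4 of these list calls: immediate early without knockout-labelled array 3 (adjusted p = 0.311) or wild-type array 2 (0.0604), cell cycle without knockout-labelled array 3 (0.311), MYC without knockout-labelled array 3 (0.0532) or wild-type array 2 (0.111), and T and NK without knockout-labelled arrays 2 (0.0973) or 3 (0.0789) or wild-type arrays 1 (0.0857) or 2 (0.0604). On the values as deposited the cell cycle (adjusted p = 0.0798), T and NK (0.134) and MYC (0.0714) lists were not called and the receptor signalling list was (0.0295). Rises and falls as deposited, then after median centring, were 10 and 0, then 3 and 0 for cell cycle, 9 and 0, then 1 and 1 for MYC, 4 and 2, then 1 and 10 for receptor signalling, and 4 and 7, then 2 and 10 for immediate early genes.

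Over all 13347 genes limma called 2277, of which 1117 were higher and 1160 lower in knockout-labelled marrow, and 538 changed at least 2-fold. The knockout-labelled arrays were brighter as deposited, which shifted the median of all genes by 0.30 and gave 3211 higher and 376 lower, while centring each array on its median gave 826 higher and 1727 lower. Of the 10 largest rises and 10 largest falls, 5 and 5 had a lower group under the filter level, so their folds depend on the pseudocount. These included the largest rise, Crhbp, a hormone-binding protein (5.05 ± 0.35), and the potassium channel gene Kcna5 (4.33 ± 0.22).

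LAP transgenic against wild-type marrow asks what the Cebpb LAP transgene changes in B220-positive cells without the Blnk knockout label. Cebpb rose 20.6-fold (4.36 ± 0.16, adjusted p = 1.02e-08). The other large rises included Lgals3, or galectin-3 (2.19 ± 0.27, adjusted p = 0.00116), the coagulation factor XIII subunit F13a1 (2.13 ± 0.23, adjusted p = 0.000522), the membrane-binding protein Anxa2 (2.24 ± 0.27, adjusted p = 0.00101) and the chemokine Ccl3 (2.47 ± 0.40, adjusted p = 0.00619). B3galt1, a galactosyltransferase gene, rose by 4.90 ± 0.29 (adjusted p = 3.24e-06). Of the 10 largest rises and 10 largest falls, 6 and 7 had a lower group under the filter level, B3galt1 and Ccl3 among them. Among the falls were Lax1, an adaptor that dampens antigen receptor signals (-1.56 ± 0.20, adjusted p = 0.00137), and Bend5 (-1.73 ± 0.15, adjusted p = 8.72e-05).

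Of 21 immature and mature B genes 3 fell and 0 rose, or 12 and 0 adjusted over the list alone. The median was -0.43 (camera adjusted p = 2.67e-06, 0.6 with an estimated correlation, fry 0.0753). As deposited 7 fell, and after median centring 6. Ccr7 fell by 0.77 ± 0.12 (adjusted p = 0.00566) and the complement receptor Cr2 by 1.01 ± 0.18 (adjusted p = 0.00974). In the light chain list 1 of 13 genes fell and 0 rose, on both counts. Its median was -0.40 (camera adjusted p = 0.0186, 0.395 with an estimated correlation, fry 0.0541). In the C/EBP family list of 5 genes 1 rose, Cebpb itself, or 3 adjusted over the list alone, with 0 falls and a median of 1.00 (camera adjusted p = 0.000482, adjusted p = 0.154 with an estimated correlation). Cell cycle genes rose in 2 of 28 cases, or 3 adjusted over the list alone, with 0 falls. Their median was 0.19 (camera adjusted p = 6.42e-05, 0.6 with an estimated correlation, fry 0.217).

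Monocyte and macrophage genes rose in 1 of 20 cases, or 4 adjusted over the list alone, with 0 falls. Their median was 0.70 (camera adjusted p = 6.42e-05, fry 0.217). None of the 18 neutrophil genes was called on either count, with a median of 0.77 (camera adjusted p = 0.000482, fry 0.276). Megakaryocyte genes had 0 of 8 called, or 2 higher adjusted over the list alone. The median was 0.56 (camera adjusted p = 0.00813, fry 0.217). The mean log2 signal of the neutrophil list was 10.78 on LAP transgenic array 3, against 9.06 and 8.53 on the other LAP transgenic arrays and 8.44, 8.86 and 8.44 on the wild-type arrays. For the monocyte list it was 9.39, against at most 8.28 on the other LAP transgenic and the wild-type arrays. Without array 3 the camera calls ended for neutrophil (adjusted p = 0.184) and megakaryocyte genes (adjusted p = 0.0549). In the interferon response list of 20 genes 1 fell, or 7 adjusted over the list alone. Its median was -0.27 (camera adjusted p = 0.00813, fry 0.248). That call ended without LAP transgenic array 2 (adjusted p = 0.19). Plasmacytoid dendritic cell genes fell in 1 of 9 cases, or 4 with 1 rise adjusted over the list alone. Their median was -0.44 (camera adjusted p = 0.0197, fry 0.183). Their call ended without LAP transgenic array 2 (adjusted p = 0.0926) or wild-type array 3 (adjusted p = 0.0728). Glycolysis genes rose in 1 of 12 cases, or 4 adjusted over the list alone, with a median of 0.15. The call (camera adjusted p = 0.0122, fry 0.183) ended without LAP transgenic array 3 (adjusted p = 0.0731). As deposited neither this list (adjusted p = 0.108) nor the dendritic cell list (adjusted p = 0.0589) was called. With an estimated correlation camera put every list of this paragraph at an adjusted p = 0.6.

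In all limma called 530 of 13347 genes, 280 higher and 250 lower in LAP transgenic marrow, with 111 changed at least 2-fold. Control probe sets of glyceraldehyde-3-phosphate dehydrogenase had a 3' to 5' ratio of 0.97 ± 0.08 (SD, n = 3) in LAP transgenic and 0.79 ± 0.02 in wild-type marrow, and whether this difference moved the counts was not tested. As deposited, with a median shift of -0.08, 102 were higher and 231 lower, and after median centring 233 and 339. The count fell to 169 without wild-type array 3, 170 without wild-type array 1, 240 without wild-type array 2 and 338 without LAP transgenic array 3.

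LAP knockout-labelled against wild-type marrow shows the joint change. Cell-surface genes of mature B cells were among the 10 largest falls outside the immunoglobulin segments: Fcer2a, the low-affinity IgE receptor CD23, fell by 5.96 ± 0.27 (adjusted p = 5.79e-09), Ccr7 by 4.58 ± 0.12 (adjusted p = 5.7e-11) and Btla, an inhibitory receptor, by 4.98 ± 0.18 (adjusted p = 9.83e-10). The antigen presentation genes H2-DMb2 and H2-Eb1 fell by 4.95 ± 0.16 and 4.60 ± 0.17, and Jchain, which joins secreted IgM into pentamers, fell by 5.33 ± 0.38 (adjusted p = 3.06e-07). Cebpb rose 18.7-fold, Fbp1, a gluconeogenic enzyme, rose 41.3-fold (5.37 ± 0.26, adjusted p = 1.15e-08) and F13a1 rose 16.5-fold (4.04 ± 0.23, adjusted p = 4.57e-08). Kcna5 rose by 6.86 ± 0.22 from under the filter level.

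All 21 immature and mature B genes fell, on both counts, with a median of -3.57 (camera adjusted p = 2.42e-28, adjusted p = 0.0478 with an estimated correlation). Ms4a1, the B-cell antigen CD20, fell by 3.12 ± 0.09 and the MHC class II gene H2-Aa by 3.57 ± 0.11. In the light chain list 12 of 13 fell, on both counts, with a median of -3.44 (camera adjusted p = 1.27e-11, adjusted p = 0.00619 with an estimated correlation). Iglv1 fell by 6.82 ± 0.18 and Igk, the kappa chain, by 2.89 ± 0.16. Pro-B and large pre-B genes rose in 9 of 15 cases and fell in 1, or 10 and 1 adjusted over the list alone, with a median of 1.03 (camera adjusted p = 2.79e-05, adjusted p = 0.354 with an estimated correlation). Examples are Igll1 (2.65 ± 0.15) and Bst1, a surface antigen of early B cells (1.99 ± 0.12). Of 21 B-lineage transcription factors 11 fell and 2 rose, on both counts, with a median of -0.45 (camera adjusted p = 0.00127, adjusted p = 0.354 with an estimated correlation). Klf2, a regulator of lymphocyte homing (-3.38 ± 0.16), Ikzf3, or Aiolos (-2.68 ± 0.14), and Spib (-1.24 ± 0.13) fell. As deposited 7 of the list fell and 3 rose.

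Cell cycle genes rose in 20 of 28 cases and fell in 0, or 23 and 0 adjusted over the list alone, with a median of 0.47 (camera adjusted p = 5.83e-06, adjusted p = 0.425 with an estimated correlation). The helicase gene Mcm3 rose by 0.93 ± 0.14 and the mitotic kinase gene Plk1 by 0.95 ± 0.16. After median centring 8 of the 28 rose, and as deposited 26. Every one of the 8 megakaryocyte genes rose, on both counts, with a median of 1.54 (camera adjusted p = 0.000216, adjusted p = 0.354 with an estimated correlation), for example von Willebrand factor, Vwf (1.91 ± 0.28). Neutrophil genes rose in 4 of 18 cases, or 7 adjusted over the list alone. Their median was 1.03 (camera adjusted p = 0.00938, 0.606 with an estimated correlation, fry 0.106). On the values as deposited 13 rose and this list was not called (adjusted p = 0.139), and after centring 3 rose. Plasmacytoid dendritic cell genes fell in 6 of 9 cases and rose in 1, on both counts, with a median of -0.84 (camera adjusted p = 0.00298, adjusted p = 0.354 with an estimated correlation). They included the mitochondrial subunit gene Cox6a2 (-1.60 ± 0.14) and the chemokine receptor Ccr9 (-2.27 ± 0.30), and as deposited 3 fell. Plasma cell genes fell in 4 of 8 cases and rose in 1, on both counts, with a median of -0.42 (camera adjusted p = 0.0411, adjusted p = 0.354 with an estimated correlation). Jchain and Prdm1 (-1.30 ± 0.18), the regulator of plasma cell formation, fell and the chaperone gene Mzb1 rose (0.91 ± 0.08), and the call ended without LAP knockout-labelled arrays 1 (adjusted p = 0.0597) or 2 (adjusted p = 0.0544).

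Camera called 4 more lists. MYC-responsive genes rose in 7 of 15 cases, or 8 adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.00938, adjusted p = 0.354 with an estimated correlation). Immediate early genes fell in 10 of 22 cases and rose in 2, or 10 and 3 adjusted over the list alone, with a median of -0.52 (camera adjusted p = 0.00938, adjusted p = 0.425 with an estimated correlation). Adhesion and migration genes fell in 6 of 12 cases and rose in 3, or 6 and 4 adjusted over the list alone, with a median of -0.40 (camera adjusted p = 0.0152, adjusted p = 0.354 with an estimated correlation). Glycolysis genes rose in 7 of 12 cases and fell in 1, or 8 and 1 adjusted over the list alone, with a median of 0.46 (camera adjusted p = 0.0268, adjusted p = 0.486 with an estimated correlation). That call ended without LAP knockout-labelled array 1 (adjusted p = 0.0857) and as deposited (0.0633).

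The number of genes called was 4165 of 13347, with 2208 higher, 1957 lower and 1206 changed at least 2-fold. As deposited, with a median shift of 0.36, 4726 were higher and 785 lower, and after median centring 1757 and 2361.

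**Figure D2:**
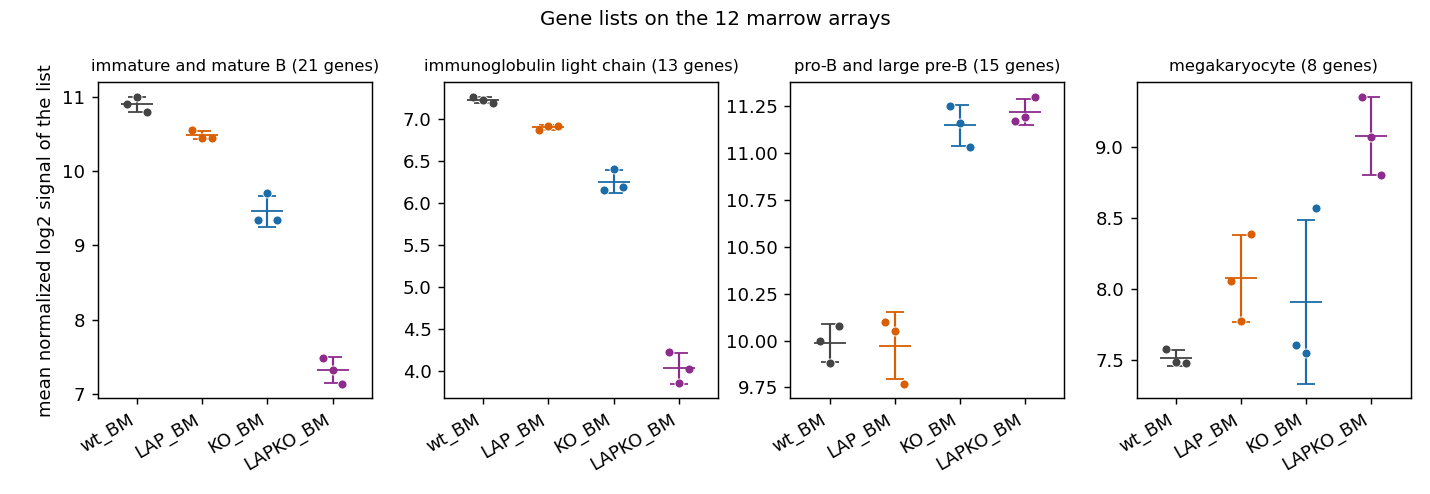
Mean normalized log2 signal of 4 gene lists on each of the 12 marrow arrays; points are arrays and bars are the group mean ± SD (n = 3). Immature and mature B genes were at least 10.79 on wild-type arrays and between 7.14 and 7.49 on LAP knockout-labelled arrays, light chain genes between 7.19 and 7.27 and between 3.85 and 4.22, pro-B genes between 9.88 and 10.08 and between 11.17 and 11.30, and megakaryocyte genes between 7.48 and 7.58 and between 8.80 and 9.35.

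LAP knockout-labelled against knockout-labelled marrow gives the LAP change under the Blnk knockout label. Cebpb rose 25.1-fold (4.65 ± 0.16, adjusted p = 2.29e-09), Fbp1 18.2-fold (4.19 ± 0.26, adjusted p = 7.06e-07) and the chemokine Ccl9 10.3-fold (3.36 ± 0.26, adjusted p = 4.24e-06). Jchain fell by 5.35 ± 0.38 (adjusted p = 1.96e-06), lymphotoxin beta, Ltb, by 3.11 ± 0.23 (adjusted p = 3.24e-06), the early lymphoid surface antigen Ly6d by 3.10 ± 0.17 (adjusted p = 2.19e-07) and Ms4a1 by 2.67 ± 0.09 (adjusted p = 2.29e-09).

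All 21 immature and mature B genes fell, on both counts, with a median of -2.24 (camera adjusted p = 5.41e-42, adjusted p = 0.0146 with an estimated correlation). In the light chain list 11 of 13 fell, on both counts, with a median of -2.11 (camera adjusted p = 2.24e-18, adjusted p = 0.00119 with an estimated correlation). B-lineage transcription factors fell in 8 of 21 cases and rose in 1, on both counts, with a median of -0.27 (camera adjusted p = 0.000265, adjusted p = 0.386 with an estimated correlation), among them Ikzf3 (-1.45 ± 0.14), Klf2 (-1.65 ± 0.16) and Irf8 (-0.93 ± 0.10). Plasmacytoid dendritic cell genes fell in 6 of 9 cases, or 7 adjusted over the list alone, with a median of -0.90 (camera adjusted p = 1.36e-06, adjusted p = 0.184 with an estimated correlation). Adhesion and migration genes fell in 6 of 12 cases and rose in 1, or 7 and 2 adjusted over the list alone, with a median of -0.29 (camera adjusted p = 0.000501, adjusted p = 0.304 with an estimated correlation). Interferon response genes fell in 4 of 20 cases, or 6 adjusted over the list alone, for example the antiviral GTPase gene Mx1 (-1.21 ± 0.23). The median was -0.38 (camera adjusted p = 0.000501, 0.48 with an estimated correlation, fry 0.118). Megakaryocyte genes rose in 7 of 8 cases, or 8 adjusted over the list alone, with a median of 1.24 (camera adjusted p = 5.89e-06, adjusted p = 0.324 with an estimated correlation). The platelet glycoprotein gene Gp1bb rose by 1.59 ± 0.30, and the mean log2 signal of the list was 7.61, 7.55 and 8.57 on knockout-labelled arrays 1, 2 and 3.

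Camera called 4 more lists. Neutrophil genes had 0 of 18 called, on both counts, with a median of 0.75. Camera's adjusted p = 0.0122 became 0.676 with an estimated correlation and 0.372 with fry. The call ended without LAP knockout-labelled array 1 (adjusted p = 0.0957) or knockout-labelled array 1 (0.222). Cell cycle genes had 0 of 28 called, on both counts. Their median was 0.28 (camera adjusted p = 0.000117, 0.602 with an estimated correlation, fry 0.15). Glycolysis genes rose in 1 of 12 cases, or 4 adjusted over the list alone. The median was 0.26 (camera adjusted p = 0.0122, 0.537 with an estimated correlation, fry 0.0806). This call ended without LAP knockout-labelled array 1 (adjusted p = 0.103) or knockout-labelled array 1 (0.0651). In the C/EBP family list 1 of 5 genes rose, Cebpb itself, on both counts, with a median of 0.39 (camera adjusted p = 0.048, adjusted p = 0.304 with an estimated correlation). That call ended without LAP knockout-labelled arrays 1 (adjusted p = 0.0736) or 2 (0.0554) or knockout-labelled array 1 (0.0718), and with the replicate number as a block (0.0606). Of 13347 genes 1023 were called, 442 higher and 581 lower, with 314 changed at least 2-fold. As deposited 284 were higher and 422 lower, and after median centring 435 and 515. Leaving out knockout-labelled array 2 gave 537 calls, LAP knockout-labelled array 2 gave 662, and knockout-labelled array 1 also gave 662.

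LAP knockout-labelled against LAP transgenic marrow gives the change with the Blnk knockout label in cells that carry LAP. Erg rose 14.4-fold (3.85 ± 0.15, adjusted p = 3.15e-09), Fbp1 20.3-fold (4.35 ± 0.26, adjusted p = 9.2e-08) and Nlrc3, a NOD-like receptor family gene, 10.9-fold (3.45 ± 0.16, adjusted p = 1.09e-08). Jchain fell by 5.97 ± 0.38 (adjusted p = 1.32e-07), Egr3 fell by 4.64 ± 0.22 (adjusted p = 1.09e-08) and Rasgrp1 by 4.48 ± 0.12 (adjusted p = 2.86e-10). All 21 immature and mature B genes fell, on both counts, with a median of -3.29 (camera adjusted p = 3.65e-29, adjusted p = 0.044 with an estimated correlation), and 12 of 13 in the light chain list, on both counts, with a median of -3.05 (camera adjusted p = 3.47e-12, adjusted p = 0.00524 with an estimated correlation). Pro-B and large pre-B genes rose in 11 of 15 cases and fell in 0, on both counts, with a median of 0.89 (camera adjusted p = 3.58e-06, adjusted p = 0.256 with an estimated correlation). One of them was Dntt, the terminal transferase of immunoglobulin joints (2.99 ± 0.24). Immediate early genes fell in 12 of 22 cases and rose in 2, or 13 and 2 adjusted over the list alone, with a median of -0.90 (camera adjusted p = 0.000635, adjusted p = 0.427 with an estimated correlation). Nfkbia, the NF-κB inhibitor, fell by 1.21 ± 0.10 and the ERK phosphatase gene Dusp6 rose by 1.12 ± 0.15. MYC-responsive genes rose in 9 of 15 cases and fell in 0, or 10 and 0 adjusted over the list alone, with a median of 0.37 (camera adjusted p = 0.00133, adjusted p = 0.256 with an estimated correlation). As deposited 15 of these rose, and of the immediate early genes 9 fell and 5 rose.

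Camera called 6 more lists. B-lineage transcription factors fell in 9 of 21 cases and rose in 4, or 12 and 4 adjusted over the list alone, with a median of -0.43 (camera adjusted p = 0.00333, adjusted p = 0.503 with an estimated correlation). Adhesion and migration genes fell in 7 of 12 cases and rose in 0, or 7 and 3 adjusted over the list alone, with a median of -0.38 (camera adjusted p = 0.00153, adjusted p = 0.256 with an estimated correlation). Megakaryocyte genes rose in 7 of 8 cases, on both counts, with a median of 0.99 (camera adjusted p = 0.0038, adjusted p = 0.503 with an estimated correlation). Plasma cell genes fell in 4 of 8 cases and rose in 1, on both counts, with a median of -0.38 (camera adjusted p = 0.02, adjusted p = 0.215 with an estimated correlation). Plasmacytoid dendritic cell genes fell in 4 of 9 cases, on both counts, with a median of -0.34 (camera adjusted p = 0.0265, adjusted p = 0.503 with an estimated correlation), and the call ended without LAP knockout-labelled array 1 (adjusted p = 0.0881) or LAP transgenic array 3 (0.0528). Cell cycle genes rose in 7 of 28 cases and fell in 1, or 8 and 1 adjusted over the list alone. Their median was 0.25 (camera adjusted p = 0.0159, 0.834 with an estimated correlation, fry 0.187). That call ended without LAP knockout-labelled array 2 (adjusted p = 0.0956) or LAP transgenic array 1 (0.0603) and as deposited (0.0795).

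The count of called genes was 3598 of 13347, with 1931 higher, 1667 lower and 978 changed at least 2-fold. With a median shift of 0.40 in the values as deposited, 5462 were higher and 565 lower, and after median centring 1583 and 1754.

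The interaction asks whether the LAP change differs between marrow with and without the Blnk knockout label. Jchain had the largest negative interaction, -5.98 ± 0.54 (adjusted p = 9.97e-05), with Ltb at -2.84 ± 0.33 (adjusted p = 0.000772), Ly6d at -2.55 ± 0.24 (adjusted p = 0.000133) and Cxcr5, a receptor for follicle entry, at -3.18 ± 0.25 (adjusted p = 3.22e-05). In LAP knockout-labelled marrow Jchain was at 4.25, near the filter level of 4.05. Under that level in LAP knockout-labelled or knockout-labelled marrow were 1 of the 10 most positive and 6 of the 10 most negative values, Cxcr5 among them. Positive values included Fbp1 (3.16 ± 0.37, adjusted p = 0.000778), the signalling adaptor gene Abi2 (1.82 ± 0.23, adjusted p = 0.000993) and the transcription factor Stat4 (1.68 ± 0.19, adjusted p = 0.000704). In the immature and mature B list 17 of 21 genes had a called negative interaction, or 21 adjusted over the list alone, with a median of -1.65 (camera adjusted p = 4.65e-34, adjusted p = 0.0279 with an estimated correlation). Ms4a1 had -2.54 ± 0.12. In the light chain list 6 of 13 were called negative, or 9 adjusted over the list alone, with a median of -1.66 (camera adjusted p = 8.13e-15, adjusted p = 0.00261 with an estimated correlation).

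For immature and mature B genes the sum of the single changes had a median of -2.01 and the joint change -3.57, with 21 of 21 genes below their own sum, and for the light chain list -1.43 and -3.44, with 13 of 13 below. The mean of the light chain list on LAP knockout-labelled arrays, 3.85 to 4.22, lay at the filter level, so the size of its joint change depends on the pseudocount. For the other lists that camera called for the interaction, the sum and the joint change were -0.19 and -0.84 for plasmacytoid dendritic cell genes, with 8 of 9 below, 0.04 and -0.40 for adhesion and migration genes, with 11 of 12 below, -0.34 and -0.45 for B-lineage transcription factors, with 14 of 21 below, and -0.18 and -0.52 for immediate early genes, with 17 of 22 below. Camera called neither the megakaryocyte list, at 0.95 and 1.54 with 0 of 8 below (adjusted p = 0.0582), nor the monocyte list, at 0.93 and 0.50 with 17 of 20 below (adjusted p = 0.0729). Pro-B and large pre-B genes had 1.06 and 1.03, with 7 of 15 below. No test was run on these counts of genes, which are not independent.

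Limma called the interaction of 231 of 13347 genes, 65 positive and 166 negative. As deposited the count was 123, with 43 and 80, and after median centring 72 and 118. It was 133 without knockout-labelled array 2, 139 without wild-type array 1, 139 without wild-type array 3, 146 without LAP knockout-labelled array 3 and 370 without knockout-labelled array 3.

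BLNK-labelled against empty-vector LB31 asks what changes when Blnk cDNA is, per the labels, introduced into the leukaemia line. The chemokine gene Ccl3 rose 33.0-fold (5.04 ± 0.34, adjusted p = 3.5e-07), the histone deacetylase gene Hdac9 13.4-fold (3.74 ± 0.16, adjusted p = 9.04e-09), the receptor-induced transcription factor Egr1 9.88-fold (3.31 ± 0.19, adjusted p = 9.01e-08) and Cd22, an inhibitory co-receptor of B cells, 6.18-fold (2.63 ± 0.13, adjusted p = 2.16e-08). Dntt fell by 2.90 ± 0.05 (adjusted p = 1.5e-12), Mycn, a MYC family transcription factor, by 2.21 ± 0.05 (adjusted p = 4.27e-12), lymphotoxin alpha, Lta, by 2.21 ± 0.07 (adjusted p = 2.27e-10) and Ly6d by 1.91 ± 0.06 (adjusted p = 3.98e-10). The lysozyme genes Lyz1 and Lyz2 fell by 3.05 ± 0.12 and 2.45 ± 0.12.

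Pro-B and large pre-B genes fell in 8 of 12 cases and rose in 0, or 9 and 0 adjusted over the list alone, with a median of -0.28 (camera adjusted p = 3.04e-06, adjusted p = 0.0364 with an estimated correlation). Erg fell by 0.89 ± 0.07. The count depends on the scaling: as deposited 2 fell, and after median centring 5 fell and 1 rose. Genes of interleukin 7 receptor and STAT5 signalling fell in 6 of 17 cases and rose in 1, or 6 and 3 adjusted over the list alone, with a median of -0.14 (camera adjusted p = 0.0252, adjusted p = 0.16 with an estimated correlation). The kinase gene Pim1 fell by 1.05 ± 0.07 and the feedback inhibitor gene Socs3 by 0.99 ± 0.10, which with all 21 arrays in 1 fit was not called (adjusted p = 0.0726). Interferon response genes fell in 4 of 15 cases, or 6 adjusted over the list alone, with a median of -0.38 (camera adjusted p = 0.0252, adjusted p = 0.16 with an estimated correlation), and the guanylate-binding protein gene Gbp3 fell by 0.78 ± 0.08. Both of these calls ended without BLNK-labelled array 2, at an adjusted p = 0.0606 for the receptor list and 0.0574 for the interferon list, or without empty-vector array 1, at 0.0879 for each. Of the receptor list 3 fell and 1 rose as deposited, and 6 and 3 after centring, and of the interferon list 2 fell as deposited.

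In the receptor signalling list 7 of 17 genes fell and 4 rose, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.202), with a median of -0.22 and a mean of 0.02. As deposited 0 fell and 4 rose, and after centring 4 and 4. Ptpn6 rose by 1.55 ± 0.06 and the Src family kinase gene Blk by 1.04 ± 0.07. B-lineage transcription factors fell in 7 of 20 cases and rose in 6, or 8 and 6 adjusted over the list alone (camera adjusted p = 0.661), with a median of -0.18. As deposited 1 fell and 4 rose, with a median of 0.04 against 0.11 for all genes. Irf4, which drives light chain recombination and B-cell maturation, rose by 1.38 ± 0.07, Mef2c rose by 0.87 ± 0.08 and Spib fell by 0.91 ± 0.06. Immediate early genes rose in 5 of 20 cases and fell in 5, or 6 and 6 adjusted over the list alone (camera adjusted p = 0.952, direction down), with a median of 0.01, a mean of 0.28, Egr2 at 3.20 ± 0.28 and Dusp5 at -1.22 ± 0.08. As deposited 3 rose and 1 fell. The light chain list had 3 of 6 genes higher and 0 lower, on both counts, with a median of 0.59 (camera adjusted p = 0.0984). It was called with fry (adjusted p = 0.0184), as deposited (0.0477) and without empty-vector array 2 (0.0248). Igk rose by 0.84 ± 0.16, a call that the mean of its probe sets did not give (adjusted p = 0.62), and the kappa variable segment Igkv4-68 rose by 0.80 ± 0.14. Immature and mature B genes rose in 2 of 15 cases and fell in 2, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.661), with the B-cell surface protein gene Cd72 at 0.86 ± 0.05.

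Of 13024 genes 2077 were called, 960 higher and 1117 lower, with 173 changed at least 2-fold. As deposited, with a median shift of 0.11, 358 were higher and 147 lower, and after median centring 2005 and 697, so the balance of rises and falls in LB31 depended on the scaling.

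YF-labelled against empty-vector LB31 is the comparison with the loss-of-function mutant. Mycn fell by 1.66 ± 0.05 (adjusted p = 3.48e-10), a 3.16-fold change. The other named changes were small: Hdac9 rose 1.91-fold (0.94 ± 0.16, adjusted p = 0.034), Lta fell by 0.50 ± 0.07 (adjusted p = 0.0189) and Dntt by 0.34 ± 0.05 (adjusted p = 0.0235). With all 21 arrays in 1 fit Mycn was at an adjusted p = 0.0625. Leaving out YF-labelled arrays 1, 2 or 3 or empty-vector array 3 ended the calls of Hdac9 (adjusted p = 0.133, 0.142, 0.106 and 0.111), Lta (0.0739, 0.0994, 0.0792 and 0.0788) and Dntt (0.125, 0.126, 0.093 and 0.11), and empty-vector array 2 also that of Hdac9 (0.0928). As deposited Lta was at -0.10 (adjusted p = 0.726) and Dntt at 0.07 (adjusted p = 0.803). The interleukin 7 receptor list had 1 of 17 genes lower, Mycn, or 2 adjusted over the list alone, with a median of -0.06 that became 0.32 as deposited, as for all genes, and 0.01 after centring (camera adjusted p = 0.304, fry adjusted p = 0.00257). None of the 28 cell cycle genes was called, or 4 higher adjusted over the list alone, with a median of 0.07 (camera adjusted p = 0.0273, adjusted p = 0.476 with an estimated correlation), and 7 rose as deposited. Glycolysis genes fell in 1 of 12 cases, or 3 adjusted over the list alone, with a median of -0.11 that became 0.28 as deposited, against 0.32 for all genes (camera adjusted p = 0.0317, adjusted p = 0.732 with an estimated correlation).

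Limma called 42 of 13024 genes, 16 higher and 26 lower, of which 2 changed at least 2-fold. As deposited, with a median shift of 0.32, the split was 574 and 20, and after median centring 40 and 7. The count was 1 without YF-labelled array 2 or 3, 4 without YF-labelled array 1, 2 without empty-vector array 3, 15 without empty-vector array 2 and 1116 without empty-vector array 1, and without YF-labelled array 1, YF-labelled array 2 or empty-vector array 1 the cell cycle call ended (adjusted p = 0.112, 0.0565 and 0.256), as the glycolysis call did without these or either other empty-vector array (adjusted p = 0.112, 0.0906, 0.0626, 0.157 and 0.0667).

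BLNK-labelled against YF-labelled LB31 compares the introduced cDNAs with each other. Ccl3 rose 13.5-fold (3.75 ± 0.34, adjusted p = 9.16e-06), Egr1 6.17-fold (2.63 ± 0.19, adjusted p = 1.16e-06) and Cd22 5.23-fold (2.39 ± 0.13, adjusted p = 9.79e-08) in BLNK-labelled cells. Serpinb1a, a protease inhibitor gene, rose 3.82-fold (1.93 ± 0.10, adjusted p = 8.42e-08). Dntt fell by 2.56 ± 0.05 (adjusted p = 7.59e-12), Lta by 1.71 ± 0.07 (adjusted p = 5.36e-09) and Ly6d by 1.65 ± 0.06 (adjusted p = 5.36e-09). Mycn, which had fallen with both cDNAs, was lower by -0.55 ± 0.05 (adjusted p = 5.52e-06) with BLNK than with YF, a call that ended with all 21 arrays in 1 fit (adjusted p = 0.491).

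Pro-B and large pre-B genes fell in 7 of 12 cases and rose in 0, or 8 and 0 adjusted over the list alone, with a median of -0.21 (camera adjusted p = 2.62e-07, adjusted p = 0.0242 with an estimated correlation), Bst1 by 0.64 ± 0.04. As deposited 3 fell, and after median centring 4 fell and 1 rose. Interferon response genes fell in 4 of 15 cases, or 5 adjusted over the list alone, with a median of -0.20 (camera adjusted p = 0.0211, adjusted p = 0.181 with an estimated correlation), Gbp3 by 0.68 ± 0.08. The interleukin 7 receptor list had 5 of 17 genes lower and 2 higher, or 8 and 2 adjusted over the list alone, with a median of -0.20 (camera adjusted p = 0.034, adjusted p = 0.181 with an estimated correlation). Its call ended without BLNK-labelled array 2 (adjusted p = 0.0664). As deposited 5 were lower and 0 higher. The light chain list had 2 of 6 genes higher and 0 lower, on both counts, with a median of 0.59 (camera adjusted p = 0.0402, adjusted p = 0.182 with an estimated correlation). Without BLNK-labelled array 1 (adjusted p = 0.131), YF-labelled array 1 (0.136) or YF-labelled array 2 (0.0687) the light chain call ended. Monocyte genes fell in 3 of 10 cases, or 4 adjusted over the list alone, with a mean of -0.56 and a median of -0.03 that became 0.05 after centring, against 0.08 for all genes (camera adjusted p = 0.0402, adjusted p = 0.182 with an estimated correlation). Lyz1 fell by 2.56 ± 0.12 and Lyz2 by 2.02 ± 0.12, and the list's call ended without BLNK-labelled array 2 (adjusted p = 0.0914) and with the replicate number as a block (0.0613). Receptor signalling genes fell in 5 of 17 cases and rose in 3, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.458), with a median of -0.03, a mean of 0.07 and Ptpn6 at 1.44 ± 0.06. After centring 3 fell and 5 rose. B-lineage transcription factors fell in 7 of 20 cases and rose in 4, or 7 and 5 adjusted over the list alone (camera adjusted p = 0.339, fry adjusted p = 0.0418), or 4 and 1 as deposited and 5 and 6 after centring, with Irf4 at 1.16 ± 0.07 and Tcf3, the gene of E2A, at -0.55 ± 0.06.

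Of 13024 genes 1177 were called, 512 higher and 665 lower, with 93 changed at least 2-fold. As deposited, with a median shift of -0.18, 66 were higher and 486 lower, and after median centring 959 and 528. The count was 771 without YF-labelled array 2 and 772 without YF-labelled array 3.

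**Figure D3:**
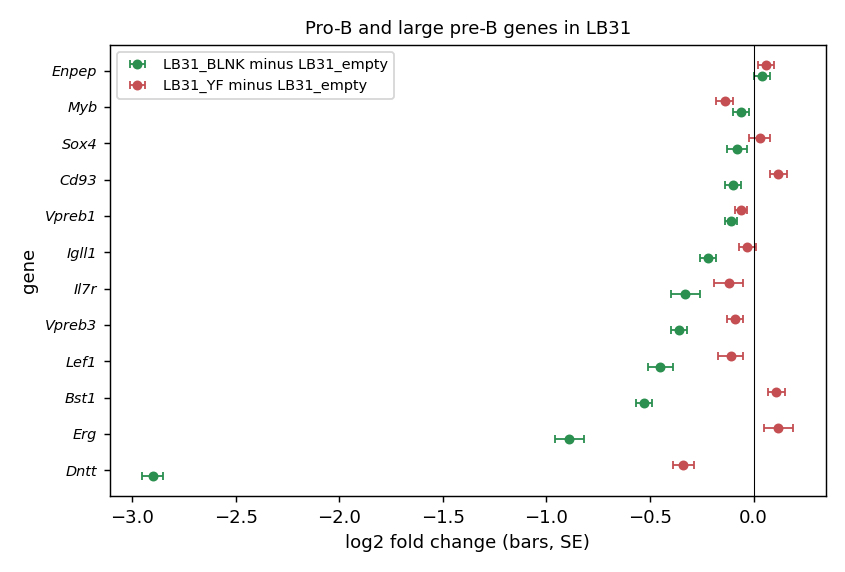
Log2 change ± SE of the 12 measured pro-B and large pre-B genes in BLNK-labelled and in YF-labelled LB31, each against empty-vector LB31 (n = 3 arrays per group). Dntt stands apart at -2.90 with BLNK and -0.34 with YF.

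Empty-vector LB31 against knockout-labelled marrow compares leukaemia with cells of its Blnk label. Culture, clonality and the sort also differ, and perhaps LAP, given the Cebpb signal. Mycn was 276.0-fold higher in LB31 (8.11 ± 0.30, adjusted p = 3.63e-15), Myc, the growth-promoting transcription factor, rose by 3.72 ± 0.16, and Aldh1a7, an aldehyde dehydrogenase gene, by 7.75 ± 0.28 (adjusted p = 2.16e-15). The recombinase gene Rag1 fell by 9.72 ± 0.21 (adjusted p = 7.92e-19), Rag2 by 6.91 ± 0.19, Ms4a1 by 8.72 ± 0.18 (adjusted p = 4.95e-19) and the integrin ligand gene Vcam1 by 8.97 ± 0.31 (adjusted p = 9.86e-16). Of the 10 largest rises and 10 largest falls, 7 and 9 had a lower group under the filter level.

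All 21 immature and mature B genes were lower in LB31, on both counts, with a median of -3.99 (camera adjusted p = 7.25e-13, adjusted p = 0.0269 with an estimated correlation). Pro-B and large pre-B genes fell in 10 of 15 cases and rose in 2, or 11 and 2 adjusted over the list alone, with a median of -1.06 (camera adjusted p = 0.00198, adjusted p = 0.217 with an estimated correlation), and after median centring 8 fell and 5 rose. Il7r, the interleukin 7 receptor, fell by 1.88 ± 0.09. B-lineage transcription factors fell in 18 of 21 cases and rose in 1, or 18 and 2 adjusted over the list alone, with a median of -1.29 (camera adjusted p = 2.02e-05, adjusted p = 0.17 with an estimated correlation). Receptor signalling genes fell in 12 of 17 cases and rose in 1, or 13 and 1 adjusted over the list alone, with a median of -0.77 (camera adjusted p = 0.00129, adjusted p = 0.172 with an estimated correlation). The riser was Cd79a, a signalling chain of the receptor (1.90 ± 0.09), and the kinase gene Syk fell by 2.36 ± 0.11. After centring 9 of the list fell and 5 rose. MYC-responsive genes rose in 14 of 15 cases, or 15 adjusted over the list alone, with a median of 1.73 (camera adjusted p = 7.54e-08, adjusted p = 0.0269 with an estimated correlation), Srm by 2.99 ± 0.08. Interleukin 7 receptor and STAT5 genes rose in 11 of 17 cases and fell in 3, or 13 and 3 adjusted over the list alone, with a median of 0.88 (camera adjusted p = 0.00391, adjusted p = 0.111 with an estimated correlation). Glycolysis genes rose in 9 of 12 cases and fell in 2, on both counts, with a median of 1.11 (camera adjusted p = 0.00198, adjusted p = 0.217 with an estimated correlation), the pyruvate kinase gene Pkm by 2.02 ± 0.08. Adhesion and migration genes fell in 11 of 12 cases, on both counts, with a median of -2.08 (camera adjusted p = 3.84e-05, adjusted p = 0.0498 with an estimated correlation), Cxcr4, the receptor that holds cells in marrow, by 1.90 ± 0.09.

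Neutrophil genes fell in 17 of 18 cases with a median of -4.16 (camera adjusted p = 3.49e-06, adjusted p = 0.21 with an estimated correlation), and the calprotectin gene S100a8 fell by 9.97 ± 0.35. Monocyte genes fell in 18 of 20 cases with a median of -3.82 (camera adjusted p = 2.01e-07, adjusted p = 0.172 with an estimated correlation), erythroid genes in 8 of 9 with a median of -4.36 (camera adjusted p = 0.00233, adjusted p = 0.224 with an estimated correlation) and megakaryocyte genes in 7 of 8 with a median of -3.89 (camera adjusted p = 0.000753, adjusted p = 0.17 with an estimated correlation). T and NK cell genes fell in 11 of 16 cases with a median of -1.75 (camera adjusted p = 0.00233, adjusted p = 0.152 with an estimated correlation). Interferon response genes fell in 16 of 20 cases and rose in 1 with a median of -1.54 (camera adjusted p = 0.000207, adjusted p = 0.172 with an estimated correlation). Adjusted over the list alone these 6 counts did not change. Xist, the RNA that silences the second X chromosome of female cells, had a mean log2 signal of 12.65 ± 0.04 (SD, n = 3) in wild-type, 12.80 ± 0.04 in LAP transgenic, 12.79 ± 0.04 in knockout-labelled and 12.87 ± 0.03 in LAP knockout-labelled marrow and fell by 8.16 ± 0.24 in LB31, where the 2 measured sex-linked genes had 1 fall and 0 rises, on both counts (camera adjusted p = 0.18).

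Camera also called plasmacytoid dendritic cell genes, of which 7 of 9 fell and 1 rose, on both counts, with a median of -2.42 (camera adjusted p = 0.0197, adjusted p = 0.174 with an estimated correlation), and stem and progenitor genes, of which 7 of 10 fell, on both counts, with a median of -1.38 (camera adjusted p = 0.0197, adjusted p = 0.17 with an estimated correlation). In the ER and amino acid stress list 9 of 16 rose and 3 fell, on both counts, with a median of 0.80 (camera adjusted p = 0.0483, adjusted p = 0.188 with an estimated correlation). That call ended without empty-vector arrays 1 (adjusted p = 0.0522) or 2 (0.0521) or knockout-labelled array 3 (0.0755), and with the replicate number as a block (0.0538).

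Limma called 8697 of 14653 genes, 4309 higher and 4388 lower in LB31, and 4407 changed at least 2-fold. As deposited, with a median shift of -0.42, 1879 were higher and 6332 lower, and after median centring, with a shift of 0.38, 6047 and 3157.

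Several comparisons can be set against each other across genes, which are not independent replicates. Log2 changes of knockout-labelled against wild-type marrow and of BLNK-labelled against YF-labelled LB31, which share no array, correlated at r = -0.13 and rho = -0.09 over 12049 genes. Of the 410 genes called in both, 177 were higher in knockout-labelled marrow and lower with BLNK, where 56.4 would be expected of independent lists, and 109 were lower and higher, where 45.8 would be. Both higher were 51 genes (43.6 expected) and both lower 73 (59.2 expected). Against the empty vector in place of YF, r was also -0.13, with 248 genes higher and lower (94.5 expected) and 148 lower and higher (85.6 expected), beside 107 both higher (81.5 expected) and 115 both lower (99.2 expected).

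**Figure D4:**
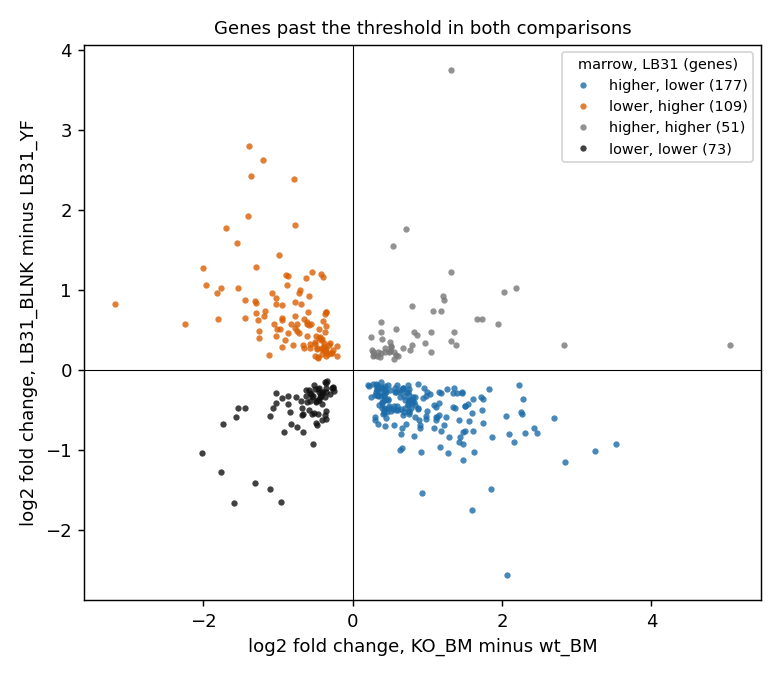
Log2 change of the 410 genes called in both comparisons, knockout-labelled minus wild-type marrow on the x axis and BLNK-labelled minus YF-labelled LB31 on the y axis; each point is a gene. The quadrant higher and lower holds 177.

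The LAP change correlated at r = 0.33 and rho = 0.29 over 13347 genes between marrow with and without the Blnk knockout label. Called in both were 74 higher genes (9.27 expected) and 99 lower genes (10.9 expected), with 6 (12.2 expected) and 8 (8.28 expected) of opposite direction. The change with the Blnk knockout label correlated at r = 0.65 and rho = 0.53 between marrow without and with LAP, with 833 genes higher in both (162 expected) and 812 lower in both (145 expected), and 16 (139.5 expected) and 7 (168 expected) of opposite direction. These pairs of comparisons share no array. BLNK and YF were each compared with the same 3 empty-vector arrays, and their changes correlated at r = 0.52 and rho = 0.53, where 100 simulations without any effect gave 0.50 and 0.45. The covariance was 0.061 against 0.033 simulated, a difference of 0.028. Called in both were 11 higher genes (1.18 expected of independent lists) and 18 lower genes (2.23 expected), with 0 of opposite direction (1.92 and 1.37 expected). Since 3 controls cannot be split with 2 on each side, part of the excess may come from the shared controls.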

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

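The comparisons with other splits of the arrays were planned before the data were examined, while the 8 tests of the 3 patterns weighed here were chosen after the results had been seen. The interaction stood out because the LAP change differed between marrow with and without the Blnk knockout label in 231 genes. The lists that camera called for it had median interactions of -1.65 (immature and mature B genes, adjusted p = 0.0279 with an estimated correlation), -1.66 (light chain list, adjusted p = 0.00261 with an estimated correlation), -0.20 (B-lineage transcription factors, adjusted p = 0.7 with an estimated correlation), -0.41 (immediate early genes, adjusted p = 0.7 with an estimated correlation), -0.65 (plasmacytoid dendritic cell genes, adjusted p = 0.395 with an estimated correlation) and -0.28 (adhesion and migration genes, adjusted p = 0.199 with an estimated correlation). Fry did not call the transcription factors (adjusted p = 0.125) or the immediate early genes (adjusted p = 0.411). Leaving out single arrays ended the call of the transcription factors 4 times, at most at an adjusted p = 0.103 without LAP transgenic array 1, and of the immediate early genes 6 times, at most at 0.266 without knockout-labelled array 2. The control probe sets for 18S ribosomal RNA had a mean 6.76 times as high on the LB31 arrays as on the marrow arrays.

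For the interaction, 100 assignments of the 12 marrow arrays to groups, the real one among them, were run, and 1 gave at least as many genes, the real one with 231. The highest of the others gave 42. Shuffling all 4 labels also mixes the single changes into the spread within groups, which lowers the counts, so these assignments do not settle whether chance alone would give 231. Each other comparison has only 10 splits of its 6 arrays, too few for a share under 0.05, and 1 of 10 reached the real count in every one. The real count and the highest other were 2277 and 0 for knockout-labelled against wild-type marrow, 530 and 9 for LAP transgenic against wild-type, 4165 and 1 for LAP knockout-labelled against wild-type, 1023 and 0 against knockout-labelled, and 3598 and 0 against LAP transgenic. In LB31 they were 2077 and 0 for BLNK against empty vector, 42 and 0 for YF against empty vector, 1177 and 0 for BLNK against YF, and 8697 and 0 for LB31 against marrow.

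Immature and mature B genes and the light chain list were lower in LAP knockout-labelled marrow than the sum of the single changes. The scaling is excluded, as the median interaction of these 34 genes lay below the bound of -1 in all 3 scalings. Minus that of all genes, which cancels array shifts, it was at most -1.67 (interquartile range up to 1.29). LAP transgenic array 3 is excluded at -1.72 (1.30) without it. From knockout-labelled marrow, Pax5, Ebf1, Cd79a, Cd79b, Ighm, Pou2af1 and Ptprc changed by a median of -0.27 (range -0.34 to 0.16, bound -0.5). This argues against B-cell loss alone, but a smaller loss stays open (2 called lower). An earlier average stage of the B cells, or lower expression in each cell, could both give the pattern, and these arrays cannot separate them. Counting the stages by flow cytometry and measuring the genes within a sorted stage would.

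The 2 Cebpb probe sets moved apart between LB31 and marrow. More of a transcript that both measure cannot alone give a pattern in which the other probe set changed by -2.43 ± 0.40 (SE). This follows from how the pattern was picked and is no independent test. The representing probe set differed from LAP knockout-labelled marrow by 0.31 ± 0.13 (adjusted p = 0.0511), but that closeness is part of what stood out and so tests nothing. RNA of the LAP transgene in LB31, where the labels name none, and another Cebpb transcript read by only 1 of the probe sets both stay open. A PCR for the transgene in LB31 DNA would decide.

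On LAP transgenic array 3, neutrophil, monocyte, erythroid and megakaryocyte genes were higher than on the other LAP transgenic arrays, by medians of 1.88, 1.13, 2.03 and 0.52. S100a9, a calprotectin gene of neutrophils, was at 13.66 against 12.79 and 12.28, and of the globin genes Hbb-b2 was higher, at 8.87 against 7.22 and 6.31, and Hba-a2 lower, at 6.31 against 7.05 and 6.67. The scaling is excluded, since the neutrophil median as deposited was 1.86. A lower share of B cells raising all other types alike stays open. Medians of 8 lists spread over 2.04 (bound 1), but plasma (-0.01) and plasmacytoid dendritic cells (0.00), the lowest, may carry B220. RNA of other marrow cells left by the B220 sort also stays open, as the pattern's medians test nothing. So does expression of the raised genes by B-lineage cells (not tested).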

How the results depend on the processing

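Leaving out arrays, the scalings and the other settings were planned before the data were examined, except the values as deposited, which were the setting fixed in advance and were replaced, before any group was tested, because the arrays were not on 1 scale; they came back as an alternative after the data had been seen. Of 495 values of named genes, 429 were called, and 361 of the 495, called or not, kept their state and direction in every setting. A call was lost in at least 1 setting for 97 and the sign turned for 7. Lost calls numbered 45 with other arrays in the fit, 44 without the trend, 34 as deposited, 25 with the mean of probe sets, 23 without a filter, 21 after median centring, 11 with every probe set, 8 with the block, 4 with a pseudocount of 1, 1 with array weights, and 0 with the other pseudocount or the 60th percentile. Leaving out 1 array ended the call of 60.

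As deposited all genes of YF against empty vector shifted by a median of 0.32. That took 6 falls above 0, all still below the shift: Vim 0.02, Selenop 0.04, Lxn 0.05, Prpsap1 0.05, Dntt 0.07 and Aldoa 0.07. It did the same to the glycolysis list, at 0.28 (camera adjusted p = 0.617). Sox4 in LB31 against marrow turned to 0.09 (adjusted p = 0.656) with the mean of its probe sets.

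Counts of called genes moved by over 1.5 times as follows. For knockout-labelled against wild-type marrow 2277 became 3587 as deposited and 3811 over every probe set. For LAP transgenic against wild-type, 530 became 333 as deposited, 301 without the trend, 1034 with array weights and 1213 with all 21 arrays in the fit. For LAP knockout-labelled marrow, 4165 against wild-type became 7601 over every probe set, 1023 against knockout-labelled became 1715 with weights and 1548 with all arrays, and 3598 against LAP transgenic became 6027 as deposited and 6357 over every probe set. The interaction's 231 became 123 as deposited, 365 over every probe set, 145 without the trend, 600 with weights and 610 with all arrays. BLNK against empty vector went from 2077 to 505 as deposited, 3373 over every probe set, 1244 without the trend and 926 with all arrays. YF against empty vector went from 42 to 594 as deposited, 18 without a filter, 76 at the 60th percentile, 26 with the mean of probe sets, 67 over every probe set, 1 without the trend, 357 with weights and 8 with all arrays. BLNK against YF went from 1177 to 552 as deposited, 1886 over every probe set, 679 without the trend and 475 with all arrays. LB31 against marrow went from 8697 to 19213 over every probe set. Every probe set on its own tests more features, so its counts are not of genes.

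With 1 array left out, the counts ran from 1589 to 1958 for knockout-labelled against wild-type marrow, 169 to 530 for LAP transgenic, 3304 to 3553, 537 to 1381 and 2776 to 3495 for LAP knockout-labelled against wild-type, knockout-labelled and LAP transgenic, 133 to 370 for the interaction, 1481 to 2813 for BLNK against empty vector, 1 to 1116 for YF, 771 to 851 for BLNK against YF and 8192 to 8387 for LB31 against marrow.

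In the same order of the 10 comparisons, 7, 11, 13, 11, 11, 6, 3, 2, 5 and 17 of 26 lists were called. With an estimated correlation 0, 0, 2, 2, 2, 2, 1, 0, 1 and 3 were, with fry 12, 2, 18, 9, 12, 5, 10, 5, 11 and 25, and as deposited 8, 10, 13, 12, 11, 7, 9, 3, 5 and 18. With 1 array left out the lowest were 4, 8, 12, 8, 10, 4, 1, 0, 3 and 16 and the highest 11, 12, 14, 14, 12, 8, 4, 2, 5 and 18.

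The correlation of knockout-labelled marrow with BLNK against YF was -0.12 as deposited, -0.18 at the 60th percentile and -0.22 over called genes. For the LAP change with and without the Blnk knockout label these were 0.34, 0.44 and 0.51, for the change with that label 0.66, 0.78 and 0.81, and for BLNK and YF 0.51, 0.56 and 0.73. With 1 array left out they ran from -0.14 to -0.12, 0.26 to 0.35, 0.61 to 0.67 and 0.48 to 0.65.

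The replicate number as a block gave 2200, 557, 4105, 1056, 3495, 247, 2063, 39, 1153 and 7581 called genes in the same order. The same numbers of different groups correlated as low as -0.10, and in no pair of groups but LAP transgenic and LAP knockout-labelled marrow did all 3 arrays fit their own number best, so the numbers do not mark pairs. The block ended 3 list calls: monocyte for BLNK against YF (adjusted p = 0.0613), C/EBP for LAP knockout-labelled against knockout-labelled marrow (0.0606) and ER stress for LB31 against marrow (0.0538).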

Other observations

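All lists here were written before the data were examined, and their choice for this part followed the results. Genes of the Bcl2 family, which govern cell death, changed in both directions in marrow. In knockout-labelled against wild-type marrow 4 of 13 rose and 2 fell, on both counts (camera adjusted p = 0.254, fry adjusted p = 0.000519). Bcl2l2, or Bcl-w, rose by 1.40 ± 0.14 (adjusted p = 2.58e-05) and Bok by 1.38 ± 0.14 (adjusted p = 2.6e-05), while Bcl2 itself fell by 1.29 ± 0.16 (adjusted p = 9.12e-05). In LAP transgenic marrow 1 of 13 rose, on both counts: Pmaip1, the death-promoting gene Noxa, by 1.49 ± 0.13 (adjusted p = 0.000107). Camera called that list (adjusted p = 0.00813, adjusted p = 0.159 with an estimated correlation).

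Of 16 genes of ER and amino acid stress 6 rose and 1 fell in knockout-labelled against wild-type marrow, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.127). In LAP knockout-labelled marrow 7 rose and 2 fell against wild-type, on both counts (camera adjusted p = 0.316), and 5 rose and 3 fell against LAP transgenic, on both counts (camera adjusted p = 0.746).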
